A study of Mus musculus with 12 samples.

How the data were processed

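RNA of mouse embryonic fibroblasts (MEFs) was hybridised to 12 Affymetrix expression arrays in 6 groups of 2. The series' design text calls the arrays of a group biological duplicates. The groups were wild-type MEFs (WT), MEFs without both Stat5 genes (KO) and KO MEFs carrying a retroviral STAT5A vector (S5), each untreated or given growth hormone for 120 minutes. No label gives a vehicle control or a KO group with an empty vector, and each genotype corresponds to its own cells, so genotype and cell preparation cannot be separated here.

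The deposited values were read as log2 expression values, with 45101 probe sets per array. The submitters' processing notes name GCOS and RMA (robust multi-array average) and give no settings. The range from 0.99 to 15.95 is that of a log2 scale, which no label states in words. Of the probe sets, 54.3 percent had a mean below 4, and these values piled up between 2 and 2.5. Plain RMA values rarely form such a low mode, which is typical of an adjustment for probe base composition. Whether one was made is not given in the sources used here.

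Probe sets were matched to genes through the probe table supplied with the series. The 64 Affymetrix control probe sets, 932 probe sets listed with several genes and 9160 with none were left out of the tests by gene. The remaining 34945 probe sets covered 18194 genes, of which 9009 had more than 1 probe set, and the probe set with the highest mean over the 12 arrays represented the gene. Gene symbols came from a RefSeq gene table of assembly GRCm38.p6, which held 18032 of these genes and renamed 2. It served for names and for the order of neighbouring genes, and no coordinates are given because no build is named with the arrays.

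Differences were tested with limma 3.58.1 (R 4.3.3). A linear model with a mean for each of the 6 groups left 6 residual degrees of freedom, and eBayes moderated the variances with 1.2 prior degrees of freedom. P-values of limma's moderated test are two-sided and were adjusted over the genes of a comparison by the Benjamini-Hochberg method at 0.05. The 12 comparisons were the effect of growth hormone within each genotype, the differences between these effects (interactions), and the genotypes against each other without and with the hormone. SDs are between the 2 arrays of a group, and SEs come from the moderated model. The 2 arrays per group limit the precision of every value.

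A level below 4 was taken as the low mode, a bound chosen after the data were seen. Values there vary little (median residual SD 0.03, against 0.29 between 4 and 8, 0.15 between 8 and 12, and 0.08 from 12 up), because the low mode compresses differences. Where both arrays of 1 of the groups compared lay in the low mode, its level was set to 4 and the fold is given as "at least", or the log2 value as a floored difference. Interactions with such groups are given as floored differences likewise, except where the text says that the values are not floored, while their p-values come from the values as deposited. No fold is given where both did. In 6572 genes all 6 groups lay below the bound.

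A set of 24 gene lists for signalling, stress, growth, matrix, patterning and cell types that a culture can hold was tested with camera at a preset correlation of 0.01, and again with the correlation estimated from the residuals. Camera p-values were adjusted over the 24 lists of a comparison. Counts of list members are given over all genes tested and, where stated, also adjusted over the list alone. The lists, the tests, the alternatives except those named as added, and the rule for named genes were fixed before the data were examined. Under that rule the text may name, per comparison, the 12 genes with the largest rise and the 10 with the largest fall among genes past the threshold with both arrays of a group above both arrays of the other (the threshold alone for interactions), without predicted genes known only by a clone or locus number. It may also name up to 4 members of a list with the smallest adjusted p. Stat5a, Stat5b, Ghr, Jak2, Cish, Socs2, Igf1 and Bcl6 were reported whatever their values. Any other gene is said to have been chosen after its values were seen.

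Overlaps of responses are given per direction beside the number for independent lists over the 18194 genes. A one-sided Fisher exact test was planned for them, but its p-values are not used, because the comparisons share the variances of 1 fit and the lists are therefore not independent. The share of KO minus WT genes that moved back in S5 was selected on untreated arrays and measured on treated S5 and KO arrays, which are separate arrays. Its 95 percent interval treats genes as independent and is therefore too narrow.

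The tests of the growth hormone responses, of the lists and of the share that moved back were tested on simulated data, drawn around each gene's mean over the 12 arrays with its residual SD. The genotype comparisons were not simulated gene by gene. Genes to be changed in the simulated responses were drawn only from those with a mean above the low mode, without the noisiest of these. The recovered shares, those of the differences between responses included, therefore hold for such genes and not for all genes tested. Recovery of genes in the low mode or of the noisiest genes was not simulated. In the simulated response of WT MEFs to growth hormone, 76 percent of 100 genes changed by a log2 value of 1 and 97 percent of 100 changed by 2 were recovered among 18194 genes, with 9 unchanged genes called. For the response of S5 MEFs 70 percent were recovered at 1, with 7 unchanged genes called. The simulated difference between the WT and KO responses recovered 52 percent at 1 and 86 percent at 2 (6 unchanged called). The difference between S5 and KO recovered 42 percent at 1 (3 unchanged called), and that between S5 and WT 87 percent at 2 (7 unchanged called). The KO response, simulated with no change, gave 0 calls by limma among 18194 genes. A list shifted by 1 was called and 0 of the 23 other lists were.

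The alternatives were a replicate block, quantile normalization, median centring, leaving out the dimmest 40 percent of genes, the mean of a gene's probe sets, every probe set on its own, a trended and robust prior, array weights, a fit of only the groups compared, an added 2-fold minimum, leaving out each array in turn, and camera on ranks. Figures were drawn with matplotlib 3.10.9 (Python 3.11.15). Raw probe intensities were not analysed here, so background and detection were not recomputed.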

Results

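Transcript levels were measured in C57BL/6 mouse embryonic fibroblasts (MEFs), connective tissue cells grown from embryos, to ask which growth hormone responses need STAT5, the transcription factor pair STAT5A and STAT5B that the hormone's receptor activates through the kinase JAK2. The 12 arrays formed 6 groups of 2 biological duplicates. Wild-type MEFs (WT), MEFs without both Stat5 genes (KO) and KO MEFs carrying a retroviral STAT5A vector (S5) were each left untreated or given growth hormone for 120 minutes. Values are deposited log2 expression values, and the tests are limma's, over 18194 genes. The median per array lay between 2.86 and 3.0, and 44.9 to 45.8 percent of probe sets per array lay above the low mode at 4. Duplicates correlated across 10947 genes with r between 0.990 and 0.996 (genes are not independent replicates), and the SD of their differences lay between 0.26 and 0.39 on the log2 scale. The number of arrays limits the precision. The log2 difference between the 3′ and 5′ control probe sets for Gapdh, a sign of RNA or label length, was 1.52 ± 0.08 (SD, n = 4) on S5 arrays against 1.02 ± 0.15 on WT and 1.04 ± 0.08 on KO arrays (n = 4 each). For Actb the same differences were 3.09, 2.88 and 2.96.

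Stat5a, a deleted gene, was read by a probe set that stood at 11.48 ± 0.04 (SD, n = 2) in untreated WT MEFs and between 2.35 and 2.44 in the KO and S5 groups, so KO MEFs were at least 179-fold lower. Another Stat5a probe set stood at 9.88 ± 0.03 in S5 MEFs and 9.09 ± 0.08 in S5 MEFs with growth hormone, and between 2.22 and 2.35 in every other group, WT included. The S5 signal thus lay on a probe set that did not read the transcript of WT MEFs. With the mean of its probe sets Stat5a changed by -0.42 with growth hormone in S5 MEFs (adjusted p = 0.00226). The S5 response minus the KO response was then -0.4 (adjusted p = 0.0324). Stat5b, the second deleted gene, stood at 9.01 ± 0.04 in WT MEFs and at 1.94 to 1.98 in KO and S5 MEFs, at least 32.3-fold lower in KO. Where the probes lie relative to the deleted part was not analysed here. Ghr, the growth hormone receptor, lay between 13.93 and 14.10 in the 6 groups on the probe set tested, where KO minus WT was 0.07 (adjusted p = 0.346). Another Ghr probe set stood at 12.31 in KO and 11.76 in WT, and with the mean of its probe sets Ghr was 0.46 higher in KO (adjusted p = 0.00579).

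**Figure D1:**
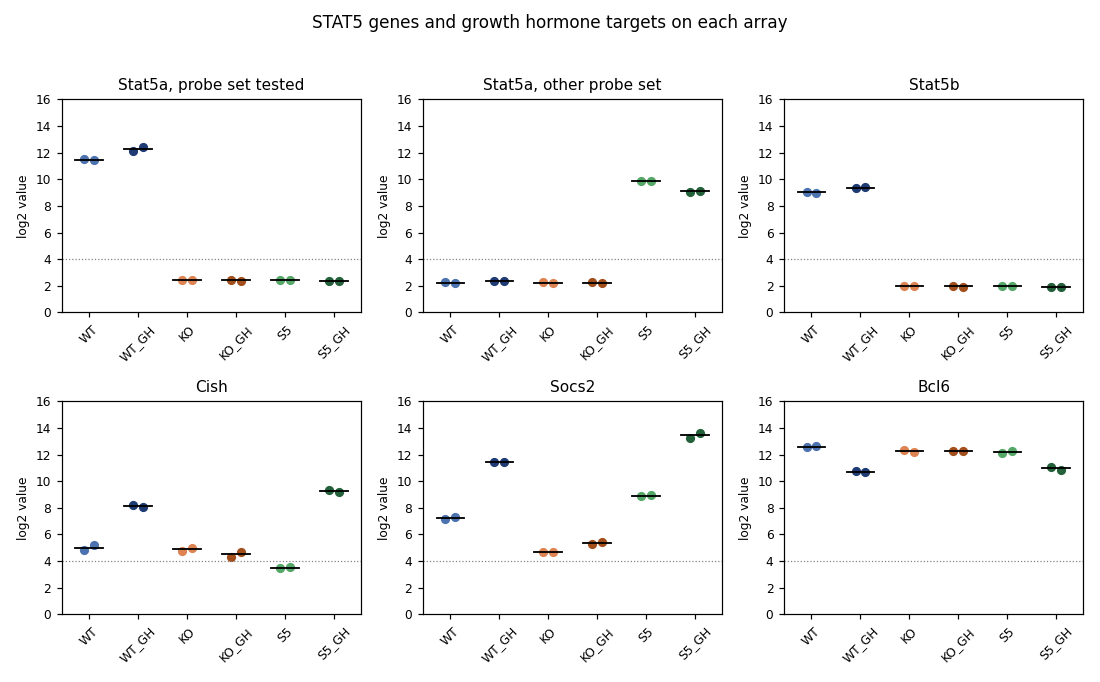
Log2 expression values (y axis, 0 to 16, dotted line at the low-mode bound of 4) of STAT5 genes and targets on each array (points, 2 per group) in the 6 groups on the x axis. Socs2 rose with growth hormone from 7.21 to 11.43 in WT and from 8.92 to 13.43 in S5 MEFs, against 4.66 and 5.34 in KO MEFs.

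Growth hormone in WT MEFs raised the STAT5 targets Socs2 and Cish and, by larger folds, the cytokine genes Il1b and Tnf. Socs2, a feedback inhibitor of cytokine receptors, rose 18.7-fold from 7.21 to 11.43 (SE of the log2 change 0.13, adjusted p = 2.7e-06), and the related inhibitor Cish rose 8.8-fold from 5.01 ± 0.23 to 8.14 ± 0.11 (SD, n = 2; adjusted p = 6.46e-05). Bcl6, a transcriptional repressor that STAT5 represses in other cells, fell 3.67-fold from 12.60 to 10.72 (adjusted p = 7.39e-05), a call lost when the mean of its probe sets was used (adjusted p = 0.0826). The other Bcl6 probe set had group means between 1.84 and 3.33, in the low mode. Losses of Bcl6 calls with the mean, here and below, therefore include a probe set without clear signal. Il1b, the cytokine interleukin 1 beta, went from 2.42 to 11.79, at least 221-fold, and Tnf, tumour necrosis factor, from 2.64 to 10.61, at least 97.6-fold. Saa3, an acute-phase protein, rose from 3.01 to 12.23. Igf1, the growth factor that the hormone induces in liver, had a log2 change of 0.25 that did not pass (adjusted p = 0.62), while Stat5a rose by 0.77 (adjusted p = 0.00259), Stat5b 1.27-fold (adjusted p = 0.0039) and Jak2 by 0.42 (adjusted p = 0.016). These 3 calls were lost in a fit of only the groups compared (adjusted p = 0.0975, 0.0877 and 0.0939). With a trended prior those of Stat5a (0.0589) and Stat5b (0.277) were lost, and with the mean of its probe sets Stat5b changed by 0.06 (adjusted p = 0.551). That of Jak2 was lost without replicate 1 of the untreated (0.079) or of the treated WT arrays (0.0732).

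Other genes also rose by large folds in WT MEFs. The colony stimulating factor Csf2 rose at least 53.3-fold, the signalling adaptor Traf1 at least 37.9-fold, the formyl peptide receptor Fpr2 at least 44.6-fold and the scavenger receptor Marco at least 20.9-fold. Cd69 and Cd83, surface markers of activated immune cells, rose 70.4-fold and 68.6-fold. The pathogen receptor Clec4e (log2 change 7.99, adjusted p = 0.000703), the chemokine Ccl4 (7.66, adjusted p = 0.000582) and Acod1, an itaconate-making enzyme of activated macrophages (7.91, adjusted p = 0.0106), also rose, each with 1 untreated WT array in the low mode. Among genes that fell were the chemokine receptor Cxcr4, at least 11.9-fold, the glycogen regulator Ppp1r3c, 8.44-fold, the polarity gene Pard6b, 7.68-fold, the RhoGAP gene Arhgap20, 6-fold and the actin-associated Palmd, at least 4.69-fold. In a fit of only the groups compared the calls of Clec4e (adjusted p = 0.0751), Ccl4 (0.0711), Acod1 (0.148), Cd83 (0.152), Cxcr4 (0.0918), Ppp1r3c (0.0874) and Pard6b (0.0627) were lost. Those of Acod1 and Cd83 were also lost without replicate 1 (0.0502 and 0.0515) or replicate 2 of the treated WT arrays (0.0564 each).

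By list, 19 of the 21 NF-kB and inflammatory genes rose in WT MEFs (19 adjusted over the list alone), with a median log2 change of 3.21 (3.16 floored) and a camera adjusted p of 7.76e-38 (0.00017 with an estimated correlation). Ccl20, a chemokine, rose by 5.59, and the floored differences of the iron-binding Lcn2 and the cytokine Il6 were 2.38 and 3.70. Of 27 interferon response genes 14 rose (15 adjusted over the list alone; adjusted p = 4.12e-19, and 0.0387 with an estimated correlation), among them the chemokine Cxcl10 by 4.89 and the antiviral genes Rsad2 by 4.22, Mx1 (floored 2.67) and Oasl1 (floored 1.77). Of 23 JAK-STAT components 7 rose and 1 fell (8 and 1 adjusted over the list alone; adjusted p = 3.45e-05, and 0.1 with an estimated correlation), with the phosphatase Ptpn2 up by 0.56 and the adaptor Sh2b3 by 0.70. Of 32 immediate early genes 8 rose and 2 fell (12 and 2 adjusted over the list alone; adjusted p = 0.00148, and 0.525 with an estimated correlation). The phosphatase gene Dusp5 rose by 2.30, and the nuclear receptor Nr4a1 fell by 1.54. Of 26 STAT5 and growth hormone targets 3 rose and 2 fell (6 and 2 adjusted over the list alone; adjusted p = 0.107), with a median of -0.02, and the kinase Pim1 rose by 1.01. The NADPH oxidase gene Nox4, chosen after its values were seen, fell by 0.71.

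The inflammatory rise stood beside a large macrophage signal on WT arrays. The mean log2 value of 14 macrophage and blood genes was 8.73 and 9.83 on the untreated WT arrays and 9.91 and 9.96 on the treated WT arrays, against 4.31 to 4.68 on KO and 3.36 to 3.79 on S5 arrays. That list had a median change of 0.50 with the hormone in WT (adjusted p = 0.0203, and 0.525 with an estimated correlation), which was -0.07 and 1.10 without replicates 1 and 2 of the untreated WT arrays. Cd14, a co-receptor of lipopolysaccharide, was its 1 member past the threshold, up by 2.69 (adjusted p = 0.0302; 1 adjusted over the list alone). Of the 294 genes that rose at least 2-fold in WT MEFs, 100 (34 percent) lay in the low mode on every KO and S5 array.

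Over all genes 1092 changed with growth hormone in WT MEFs, 557 up and 535 down, of which 294 and 171 did so at least 2-fold. The count fell to 547 without replicate 2 of the treated WT arrays, and to 266 in a fit of only the groups compared. All groups lay in the low mode for 34 of the 1092 genes. The 3′ to 5′ differences of the control probe sets also moved in WT, from 1.13 to 0.91 for Gapdh and from 3.07 to 2.69 for Actb, with no overlap between untreated and treated arrays.

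**Figure D2:**
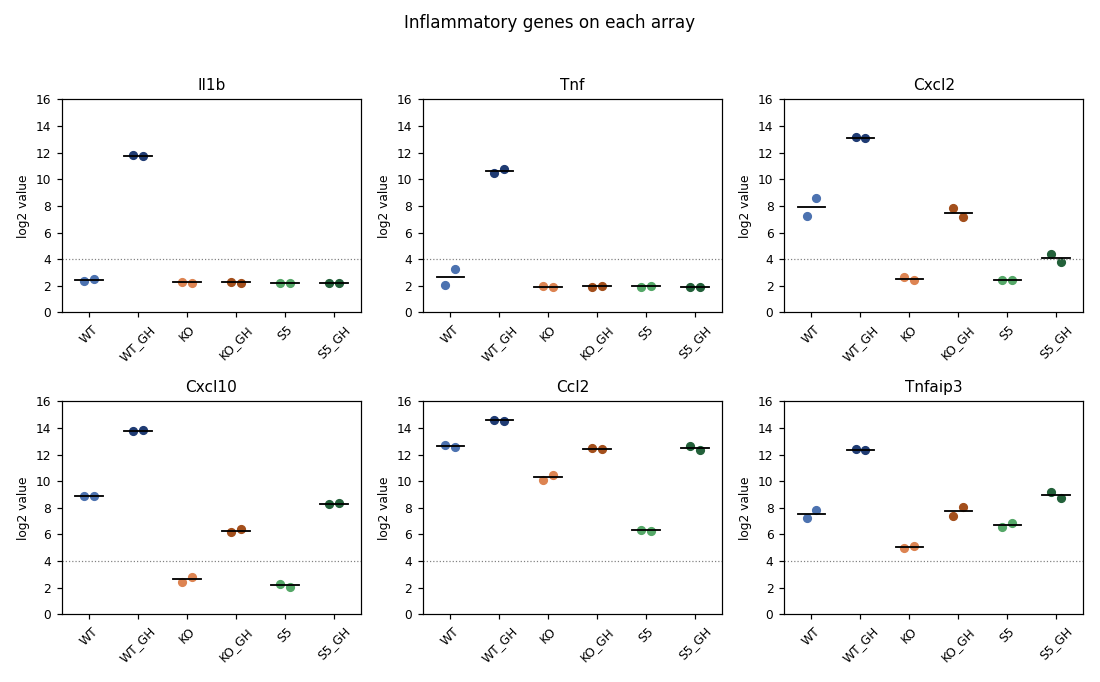
Log2 expression values (y axis, 0 to 16, dotted line at the low-mode bound of 4) of 6 inflammatory genes on each array (points, 2 per group) in the 6 groups on the x axis. Il1b went from 2.42 to 11.79 with growth hormone in WT MEFs and stayed in the low mode in KO and S5 MEFs, whereas Ccl2 reached 12.43 in KO and 12.50 in S5 MEFs with growth hormone.

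Growth hormone in S5 MEFs raised Cish at least 38.1-fold, from 3.50 to 9.25 (SE of the log2 change 0.16, adjusted p = 4.29e-06), and Socs2 22.8-fold, from 8.92 to 13.43 (adjusted p = 4.29e-06). Bcl6 fell 2.33-fold from 12.17 to 10.95 (adjusted p = 0.000868), a call lost with the mean of its probe sets (adjusted p = 0.115) and in a fit of only the groups compared (adjusted p = 0.0531). Ccl2, a monocyte chemokine, rose 72.7-fold from 6.32 to 12.50 (adjusted p = 2.17e-06), and Cxcl10 rose at least 19.8-fold. Igf1 had a change of 0.75 (adjusted p = 0.168) and Jak2 of 0.20 (adjusted p = 0.157). Igf1 passed with the mean of its probe sets (adjusted p = 0.0403) and with array weights (0.0282), and Jak2 with array weights (0.0329).

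Other large rises in S5 MEFs were those of Ikzf4, an Ikaros-family factor of lymphocytes, at least 17.2-fold, of the semaphorin receptor Plxna2, 29.8-fold, of the NF-kB cofactor Bcl3, 22.8-fold, of the growth factor carrier Igfbp3, 22.4-fold, of the protease inhibitor Serpinb1a, 20.8-fold, of the solute carrier Slc45a3, 20.1-fold, of the interferon-inducible GTPase Ifi47, at least 8.03-fold, and of the lipid transporter Mfsd2a, at least 6.59-fold. Genes that fell included the hedgehog effector Gli2, 14.7-fold (adjusted p = 0.00407), the T-box gene Tbx2, at least 3.26-fold, the cartilage regulator Sox9, 5.84-fold (adjusted p = 0.00104), and the growth factor Fgf18, 5.8-fold. The transcription factor genes Dmrta1 and Bcl11b fell 14.2-fold and 7.2-fold, and the matrix protease gene Adamts18 fell 6.49-fold. In a fit of only the groups compared the calls of Gli2 (adjusted p = 0.0934), Dmrta1 (0.116), Bcl11b (0.066), Adamts18 (0.125), Bcl3 (0.0697) and Serpinb1a (0.0724) were lost. That of Fgf18 was lost without replicate 1 (0.0854) or 2 (0.0669) of the untreated and without replicate 1 (0.0836) or 2 (0.0538) of the treated S5 arrays.

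Of the NF-kB and inflammatory genes 12 rose in S5 MEFs (14 adjusted over the list alone), with a median of 1.29 (0.96 floored) and an adjusted p of 9.94e-19 (0.00133 with an estimated correlation). Ccl7, a neighbour of Ccl2 in the chemokine cluster, rose by 3.76 and the NF-kB subunit Relb by 3.0. Of 20 genes of unfolded protein and amino acid stress 2 fell (3 adjusted over the list alone; adjusted p = 0.00515, and 0.102 with an estimated correlation), the glutathione-degrading Chac1 by 2.22 and the mitochondrial folate enzyme Mthfd2 by 0.34. Of the interferon genes 5 rose and 2 fell (5 and 4 adjusted over the list alone; adjusted p = 0.262), and of the STAT5 targets 3 rose and 2 fell (4 and 5 adjusted over the list alone; adjusted p = 0.591), with the feedback inhibitor Socs3 up by 2.53. The endothelial growth factor receptor Flt1 rose (floored 2.96), and the epithelial factor Trp63 fell (floored -1.41).

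In S5 MEFs 1433 genes changed with growth hormone, 660 up and 773 down, of which 237 and 182 did so at least 2-fold. The share of higher calls was 46.1 percent, and 32.2 percent after centring each array on its median. The count was 682 and 552 without replicates 1 and 2 of the untreated S5 arrays, 661 without replicate 1 of the treated S5 arrays, 532 in a fit of only the groups compared and 2914 with array weights. All groups lay in the low mode for 53 of the 1433 genes.

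In KO MEFs, which lack STAT5, growth hormone still raised genes of the NF-kB and inflammatory list. Cxcl2, a neutrophil chemokine, rose at least 11.2-fold from 2.51 to 7.49 (SE of the log2 change 0.42, adjusted p = 0.00867), its relatives Cxcl1 21.7-fold (adjusted p = 0.0202) and Cxcl5 at least 6.12-fold (adjusted p = 0.00178), and Cxcl10 at least 4.8-fold (adjusted p = 0.000159). Ccl2 rose 4.4-fold from 10.29 to 12.43 (adjusted p = 0.00416). Tnfaip3, a brake on NF-kB signalling, rose 6.47-fold, Relb 3.22-fold and Bcl3 at least 10.4-fold, and the nuclear receptor Nr4a3 8.02-fold (adjusted p = 0.0424). The STAT5 targets did not pass. Cish had a log2 change of -0.37 (adjusted p = 0.515), Socs2 of 0.67 (adjusted p = 0.104) and Igf1 of -0.30 (adjusted p = 0.938), and Bcl6 stood at 12.27 in both groups. Socs2 did pass, with an adjusted p of 0.0354, when either treated S5 array was left out, which changes only the pooled variance of a KO comparison.

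Fewer genes fell than rose in KO MEFs. Ptger3, a prostaglandin receptor, fell at least 2.14-fold, the tetraspanin Tspan33 3.33-fold, the growth regulator Ccdc8 2.67-fold and the tight junction gene Cldn1 2.21-fold. The disaccharidase gene Mgam fell at least 2.02-fold. Cardiac troponin Tnnt2 rose at least 2.59-fold and the endocytic regulator Micall2 3.05-fold. Fos, an immediate early gene chosen after its values were seen, had a change of -5.42 that did not pass (adjusted p = 0.114). Of the rises and falls named here for KO MEFs, those of Cxcl10, Cxcl5, Ccl2 and Ptger3 lost their calls in a fit of only the KO groups and under no other alternative. The call of Cxcl2 was also lost with array weights (adjusted p = 0.0647). The others lost theirs with array weights (adjusted p between 0.0762 for Cxcl1 and 0.357 for Nr4a3) and without single arrays, which included arrays of every group (adjusted p up to 0.127, for Nr4a3). The replicate block ended the calls of Nr4a3 (0.088), Tnnt2 (0.0855), Cldn1 (0.081), Mgam (0.0514) and of Tnfaip3, Micall2 and Ccdc8 (0.0509 each). With the mean of its probe sets Tnnt2 changed by 0.80 (adjusted p = 0.1). The call of Ccdc8 was also lost with quantile normalization (0.0662), that of Cldn1 with a trended prior (0.0714) and that of Nr4a3 with every probe set on its own (0.0514).

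Of the NF-kB and inflammatory genes 8 rose in KO MEFs (14 adjusted over the list alone), with a median of 0.89 (0.52 floored) and an adjusted p of 1.38e-20 (0.00101 with an estimated correlation). The list of JAK-STAT components was called higher (2 genes up, 4 adjusted over the list alone; adjusted p = 0.00021, and 0.116 with an estimated correlation), with the oncostatin M receptor Osmr up by 0.74 and the phosphatase Ptpn1 by 0.92. The list of unfolded protein and amino acid stress genes was called lower (1 gene down, 3 adjusted over the list alone; adjusted p = 0.000183, and 0.0401 with an estimated correlation), with Mthfd2 down by a log2 change of -0.45. The immediate early list was called lower by camera with 0 of 32 members past the threshold of limma's test over all genes (2 up and 5 down adjusted over the list alone; adjusted p = 0.000183, and 0.401 with an estimated correlation). So was the p53 and senescence list, with 0 of 19 members past it (1 up and 4 down adjusted over the list alone; adjusted p = 0.0112, and 0.116 with an estimated correlation), whereas the oxidative stress list was called higher, also with 0 of 19 (2 up adjusted over the list alone; adjusted p = 0.00614, and 0.278 with an estimated correlation). Of the interferon genes Cxcl10 alone passed (adjusted p = 0.101 for the list), and of the STAT5 targets none did (1 up adjusted over the list alone; adjusted p = 0.487 for the list).

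In KO MEFs 56 genes changed with growth hormone, 41 up and 15 down, and 1800 had an unadjusted p below 0.05. The count was 20 without replicate 1 or without replicate 2 of the untreated S5 arrays, which changes only the pooled variance, and 140 without replicate 1 of the treated KO arrays. It was 10 with array weights, 95 over genes above the low mode, and 0 by limma in a fit of the KO groups alone, where 1407 genes had an unadjusted p below 0.05. The lists for the STAT5 targets, cell cycle, extracellular matrix, smooth muscle, fibroblast identity, positional genes, imprinted genes, sex-linked genes, cholesterol synthesis, hypoxia, adipocytes, endothelium, epithelium, neural cells, skeletal muscle and cartilage, 16 in all, had no camera call in the 3 growth hormone comparisons as tested (adjusted p between 0.0557 and 0.952). Camera tests a shift in 1 direction, and of the STAT5 targets 3 rose and 2 fell in WT and likewise in S5 MEFs. For that list the lack of a call therefore does not mean a lack of response. Under alternatives 3 of the 16 lists were called in KO MEFs. Smooth muscle genes were called with camera on ranks (adjusted p = 0.0215) and without replicate 2 of the treated KO arrays (0.0157). Imprinted genes were called with quantile normalization (0.0386), without the dimmest genes (0.0352) and without replicate 2 of the untreated KO arrays (0.0295), and skeletal muscle genes without the dimmest genes (0.0287).

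The response to growth hormone differed between WT and KO MEFs at STAT5 targets and at inflammatory genes. The difference of log2 changes, WT minus KO, was 3.51 for Cish (adjusted p = 0.000443), 3.55 for Socs2 (adjusted p = 0.000104) and -1.88 for Bcl6 (adjusted p = 0.000965; 0.211 with the mean of its probe sets). The floored difference was 7.79 for Il1b, 8.23 for Saa3, 6.61 for Tnf, 5.74 for Csf2 and 5.59 for Ccl20. For Pard6b it was -3.29, a call lost in a fit of only the groups compared (adjusted p = 0.058) and without replicate 1 of the untreated KO arrays (0.0548). For Igf1 it was 0.55 (adjusted p = 0.89). Of the interferon genes 6 had a larger response in WT (16 adjusted over the list alone; adjusted p = 3.3e-21, and 0.0297 with an estimated correlation), Mx1 by a floored 2.67 and Oasl1 by a floored 1.77. Of the NF-kB genes 8 did (13 larger and 1 smaller adjusted over the list alone; adjusted p = 2.53e-21, and 0.000916 with an estimated correlation), Lcn2 by a floored 2.38 and Il6 by a floored 3.70. The STAT5 target list was called (2 larger and 1 smaller; 3 and 1 adjusted over the list alone; adjusted p = 0.00864, and 0.0951 with an estimated correlation). So were the immediate early genes (2 larger; 8 larger and 1 smaller adjusted over the list alone; adjusted p = 1.61e-10, and 0.131 with an estimated correlation; Dusp5 by 2.83) and the p53 genes (1 of 19 larger, the death receptor Fas by 2.50; 2 adjusted over the list alone; adjusted p = 0.017, and 0.116 with an estimated correlation). Over all genes 231 responses differed, 154 larger in WT and 77 smaller. Their number was 150 without replicate 1 or without replicate 2 of the untreated S5 arrays, 355 without replicate 2 of the untreated WT arrays, 129 without the dimmest genes, 125 with array weights and 116 in a fit of only the groups compared.

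Stat5a and Stat5b themselves had WT minus KO differences of 0.80 (adjusted p = 0.0238) and 0.37 (adjusted p = 0.0325), not floored, with KO values in the low mode. Floored, they are the WT changes alone. These calls were not stable. They were lost with a trended prior (0.423 and 0.896), with array weights (0.0609 and 0.0604) and in a fit of only the groups compared (0.12 and 0.161). That of Stat5b was also lost with the replicate block (0.0789), with centring (0.0796), without the dimmest genes (0.214) and with the mean of its probe sets (0.988). Without single arrays that of Stat5a stayed only for untreated WT replicate 1 and the treated WT replicates, and that of Stat5b only for replicate 1 of the untreated and treated WT arrays. Elsewhere the adjusted p lay between 0.052 and 0.0739 for Stat5a and between 0.0523 and 0.085 for Stat5b.

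Between S5 and KO MEFs the response differed by a floored 5.62 for Cish (adjusted p = 4.53e-05), 3.84 for Socs2 (adjusted p = 0.000162) and -1.22 for Bcl6 (adjusted p = 0.011; 0.255 with the mean of its probe sets and 0.0616 in a fit of only the groups compared). It differed by 5.07 for Plxna2, 4.93 for Igfbp3 and 4.05 for Ccl2, and by a floored 4.10 for Ikzf4, 2.60 for Ifi47 and 2.88 for Apln, a vascular peptide. It differed by -2.80 for Bcl11b and -2.47 for Sox9, calls lost in a fit of only the groups compared (adjusted p = 0.0697 and 0.0737), and that of Sox9 also without replicate 1 (0.0504) or 2 (0.051) of the untreated S5 arrays. Of the NF-kB genes 5 had a larger response in S5 (7 larger and 1 smaller adjusted over the list alone; adjusted p = 0.00364, and 0.171 with an estimated correlation), the adhesion molecule Vcam1 by 2.24 and Ccl7 by 2.69. For Ccl2 the levels with the hormone, given above, were close in S5 and KO MEFs. Its larger response thus came from a lower untreated level in S5. Immediate early genes (3 larger adjusted over the list alone; adjusted p = 0.00364, and 0.814 with an estimated correlation) and oxidative stress genes (1 smaller, 3 adjusted over the list alone; adjusted p = 0.0143, and 0.61 with an estimated correlation) were called at the preset correlation only. The STAT5 target list was not called (3 larger and 1 smaller; 3 and 2 adjusted over the list alone; adjusted p = 0.129), but was without the dimmest genes (adjusted p = 0.0459). In all 205 responses differed, 117 larger in S5 and 88 smaller, and 114 did in a fit of only the groups compared.

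The S5 response also differed from that of WT MEFs. Cish rose more in S5, by a floored 2.11 (adjusted p = 0.00143), while the differences of Socs2 (0.29, adjusted p = 0.633) and Bcl6 (0.66, adjusted p = 0.0594) did not pass. That of Bcl6 passed with centring (adjusted p = 0.0382), a trended prior (0.0461), array weights (0.0387) and without replicate 2 of the treated S5 arrays (0.0294). With the mean of its probe sets Socs2 differed by 1.61 (adjusted p = 0.000174). The differences for Stat5a and Stat5b, not floored, were -0.83 and -0.37, with S5 values of these probe sets in the low mode, and were lost with a trended prior (adjusted p = 0.237 and 0.68). That of Stat5b was also lost with the mean of its probe sets (0.843), without the dimmest genes (0.125) and without any of the 4 S5 arrays or replicate 2 of the untreated or treated WT arrays (0.0522 to 0.0723). Floored differences were -7.79 for Il1b, -8.23 for Saa3, -6.61 for Tnf and -6.14 for Cd69, all smaller in S5. Responses were larger in S5 by 5.17 for Serpinb1a, 4.53 for Plxna2 and 4.28 for Igfbp3, and by a floored 4.10 for Ikzf4 and 1.63 for Nppc, a natriuretic peptide of growing cartilage. The response of Ccl20 was smaller in S5 (floored -5.59) and that of Ccl2 larger by 4.24. Of the NF-kB genes 4 had larger and 9 smaller responses (4 and 11 adjusted over the list alone; adjusted p = 1.92e-05, and 0.0457 with an estimated correlation), and of the interferon genes 1 and 8 did (2 and 13 adjusted over the list alone; adjusted p = 2.61e-09, and 0.193 with an estimated correlation). Immediate early (adjusted p = 0.00629, and 0.591 with an estimated correlation), oxidative stress (0.0303, and 0.481) and macrophage genes (0.0206, and 0.597) were called at the preset correlation only. In all 532 responses differed, 256 larger in S5 and 276 smaller.

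Some list calls on growth hormone also changed with other settings. Some list calls between genotypes did so too and are not listed singly here. In WT MEFs the macrophage call was lost without replicate 1 of the untreated (adjusted p = 0.663) and without replicate 1 or 2 of the treated WT arrays (0.0681 and 0.0594), and the immediate early call without replicate 2 of the untreated WT arrays (0.452). In S5 MEFs centring ended the call of unfolded protein stress genes (0.0686) and brought a call of interferon genes (0.0165), and JAK-STAT components were called without replicate 1 of the untreated S5 arrays (0.0474). In KO MEFs the JAK-STAT call was lost without replicate 2 of the treated KO arrays (0.065). The p53 call was lost without replicate 1 of the untreated (0.128) or treated KO arrays (0.319), and the oxidative stress call without replicate 2 of the untreated KO arrays (0.427) and without the dimmest genes (0.0571). Interferon genes were called in KO MEFs without replicate 1 of the untreated (0.0246) or treated KO arrays (0.0194). Between WT and KO responses the STAT5 target call was lost on ranks (0.0669) and without replicate 2 of the treated WT arrays (0.0798). The p53 call was lost on ranks (0.186), with quantile normalization (0.0776) and without replicate 2 of the untreated (0.0699) or treated WT arrays (0.142) or replicate 1 of the untreated (0.0587) or treated KO arrays (0.243), and the macrophage list was called without replicate 2 of the untreated WT arrays (1.34e-07). Between S5 and KO responses the NF-kB call was lost on ranks (0.666) and without replicate 1 of the treated KO arrays (0.0779). The immediate early call was lost without replicate 1 of the untreated (0.141) or treated S5 arrays (0.208). The oxidative stress call was lost on ranks (0.129), with centring (0.0519), without the dimmest genes (0.0862) and without 5 of the single arrays (0.0572 to 0.238).

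Between S5 and WT responses centring ended the immediate early (0.135), oxidative stress (0.0979) and macrophage calls (0.0979). The immediate early call was also lost without replicate 2 of the treated S5 (0.0634) or untreated WT arrays (0.217), and the macrophage call without replicate 2 of the treated S5 (0.0634), replicate 1 of the untreated WT (0.446) or replicate 2 of the treated WT arrays (0.0636). The oxidative stress call was lost with quantile normalization (0.0647), without the dimmest genes (0.143) and without 4 of the single arrays (0.0597 to 0.244). Lists not called were called in some alternatives, such as endothelium without the dimmest genes (0.00971 between S5 and KO, 0.00135 between S5 and WT) and interferon genes between S5 and KO with centring (0.0415).

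Ghr, Jak2 and Igf1 had no difference between responses that passed. For Ghr these were 0.01, 0.06 and 0.05 (WT minus KO, S5 minus KO and S5 minus WT; adjusted p = 1, 1 and 0.934) and for Jak2 0.14, -0.08 and -0.22 (0.881, 1 and 0.398). For Igf1, given above for WT minus KO, they were 1.05 for S5 minus KO (adjusted p = 0.392) and 0.50 for S5 minus WT (0.77). The log2 change of Ghr with growth hormone was -0.01 in WT, 0.04 in S5 and -0.02 in KO MEFs (adjusted p = 0.911, 0.764 and 0.946), and that of Jak2 in KO MEFs was 0.28 (adjusted p = 0.206).

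The responses of WT and S5 MEFs shared 152 genes that rose and 152 that fell, against 20.2 and 22.7 for independent lists, while 19 and 15 genes moved in opposite directions. The log2 changes of genes called in either correlated with r = 0.292 across 2187 genes, which are not independent replicates. Of the 41 genes that rose in KO MEFs, 28 also rose in WT (1.26 for independent lists) and 27 in S5 (1.49), and of the 15 that fell 5 and 4 did so too (0.441 and 0.637). In opposite directions KO MEFs shared 1 rise and 1 fall with WT and 0 with S5. These comparisons share no arrays, but they share the variances of 1 fit, so that genes of low variance pass more easily in each and the lists are not independent. The WT and S5 overlap of 304 genes in both directions was 150 and 121 without replicates 1 and 2 of the untreated S5 arrays, 168 without replicate 1 of the treated S5 arrays, 173 and 165 without replicates 1 and 2 of the untreated WT arrays, and 130 without replicate 2 of the treated WT arrays. That of WT and KO, 33 genes, was 14 without replicate 1 or without replicate 2 of the untreated S5 arrays, 20 without replicate 2 of the treated WT arrays, 17 without replicate 2 of the untreated KO arrays and 57 without replicate 1 of the treated KO arrays. That of S5 and KO, 31 genes, was 14 and 15 without replicates 1 and 2 of the untreated S5 arrays and 20 without replicate 2 of the untreated KO arrays.

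A set of 36 genes differed from the KO response in the same direction in WT and S5 MEFs, 26 higher and 10 lower. Besides Cish, Socs2 and Cxcl10 it held genes that rose in both lines, such as the retinoic acid hydroxylase Cyp26b1 (floored log2 change 3.69 in WT and 2.75 in S5, and in the low mode in KO), the interferon-inducible GTPases Gbp7 (2.63 in WT, 2.91 in S5 and 0.70 in KO) and Ifi47 (2.66, a floored 3.01 and 0.40), the lipid transporter Mfsd2a (2.19 and a floored 2.72, and in the low mode in KO) and the macrophage growth factor Csf1 (1.33, 1.29 and 0.44). Bcl6 and Pcyt1b, an enzyme of phospholipid synthesis (-1.35, -1.24 and 0.24), were among the lower ones. Other members changed in KO MEFs alone. Ptger3, Kcnh1, Astn2, Egflam and Septin3 fell there, and Rbm38, Tox3 and Mdga2 rose there, all but Ptger3 with group means below 4. Of the 10 lower genes only Klhl23, AA414768, Pcyt1b and Bcl6 fell past the threshold in WT and in S5. The genes of the set that no earlier comparison names were chosen after their values were seen. Independent lists would share 0.99 and 0.372 genes. In 20 simulations with no change in any group, KO included, the highest number was 0. With so few calls there, this number cannot show how many of the real calls coincide through the shared KO arrays. Part of the excess may come from the shared KO arrays, which are too few to split. The number was 20 and 15 without replicates 1 and 2 of the untreated S5 arrays, 23 without replicate 1 of the untreated WT arrays and 68 without replicate 1 of the treated KO arrays.

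Among the genes with the largest differences between untreated KO and WT MEFs were single macrophage, sex-linked, homeobox and growth factor genes. The complement receptor C5ar1 was at least 350-fold lower in KO, the macrophage perforin Mpeg1 at least 271-fold, the myeloid adaptor Tyrobp at least 247-fold and the protease Ctss at least 353-fold. The embryonic growth factor Igf2 was at least 633-fold lower, the limb gene Hoxd13 at least 199-fold, the chemokine Cxcl14 at least 170-fold and the Y-linked gene Eif2s3y at least 294-fold, while Xist, the RNA that silences an X chromosome, was at least 91.1-fold higher. Higher in KO were also the neuropeptide Vip, at least 132-fold, its relative's receptor Adcyap1r1, at least 42.5-fold, the neural crest factor Pax3, 227-fold, the desmosome gene Dsp, 53.2-fold, the homeobox gene Lhx8, 40.3-fold, and the Wnt inhibitor Dkk2, 37.6-fold. The largest difference was that of Mycn, a growth-promoting transcription factor, at 1.78 in WT and 14.19 in KO, at least 1170-fold, on 1 of its 3 probe sets, with log2 differences of 0.19 and -0.06 on the others. Of the STAT5 targets Socs2 was lower by a log2 value of -2.54 (adjusted p = 1.22e-05) and Igf1 by -1.21 (adjusted p = 0.0145), a call lost in a fit of only the groups compared (0.0683) and without replicate 2 of the untreated WT (0.0884) or KO arrays (0.0767). Cish did not differ past the threshold (-0.14, adjusted p = 0.694). Bcl6 passed narrowly (-0.33, adjusted p = 0.0429). Its call was lost with the replicate block (0.067), quantile normalization (0.0536), the mean of its probe sets (0.733), every probe set on its own (0.0525), array weights (0.0974), only the groups compared (0.122) and without any single array but KO replicate 2 and the treated S5 arrays (0.0598 to 0.227).

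By list, all 17 cholesterol synthesis genes were lower in KO (17 adjusted over the list alone; adjusted p = 4.21e-15, and 0.00794 with an estimated correlation), for example the lanosterol synthase Lss (-2.45) and the squalene epoxidase Sqle (-1.73). Of 25 cell cycle genes 21 were lower and 1 higher (21 and 1 adjusted over the list alone; adjusted p = 8.06e-14, and 0.0464 with an estimated correlation), among them the proliferation marker Mki67 (-3.30) and the mitotic activator Cdc20 (-2.91). Of the NF-kB genes 12 were lower (13 adjusted over the list alone; adjusted p = 2.47e-08, and 0.00794 with an estimated correlation), with Ccl5 at a floored -4.87. The following lists were called only at the preset correlation. Lower were 12 of 15 smooth muscle genes (adjusted p = 1e-08, and 0.057 with an estimated correlation; myosin Myh11 floored -5.70), 11 macrophage genes (6.04e-08, and 0.127; lysozyme Lyz2 -6.67) and 16 interferon genes, with 4 higher (2.79e-06, and 0.116; Cxcl10 floored -4.90). So were 9 hypoxia genes with 1 higher (0.00105, and 0.057), 6 adipocyte genes (0.00115, and 0.0603; the fatty acid carrier Fabp4 -5.84), 10 unfolded protein stress genes with 1 higher (0.00475, and 0.057), 6 of 18 neural genes (0.00666, and 0.172; the glial factor Sox10 floored -2.02) and 9 immediate early genes with 1 higher (0.0101, and 0.383). All 4 sex-linked genes differed (0.00318, and 0.057; Uty floored -4.78, Kdm5d floored -6.20). Not called by camera were the positional genes (14 higher and 17 lower of 47, adjusted p = 0.334) and the matrix genes (5 and 10 of 27, adjusted p = 0.203). Camera tests a shift in 1 direction, so members that differ both ways cancel in it. Positional genes thus differed often between KO and WT, against 27.1 percent of all genes, but in both directions. In all 4935 genes differed, 2525 higher in KO and 2410 lower. Y-linked genes were read in WT and Xist in KO MEFs, so by these genes the sex of the cells differed. Sex therefore cannot be separated from genotype in comparisons with WT MEFs.

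**Figure D3:**
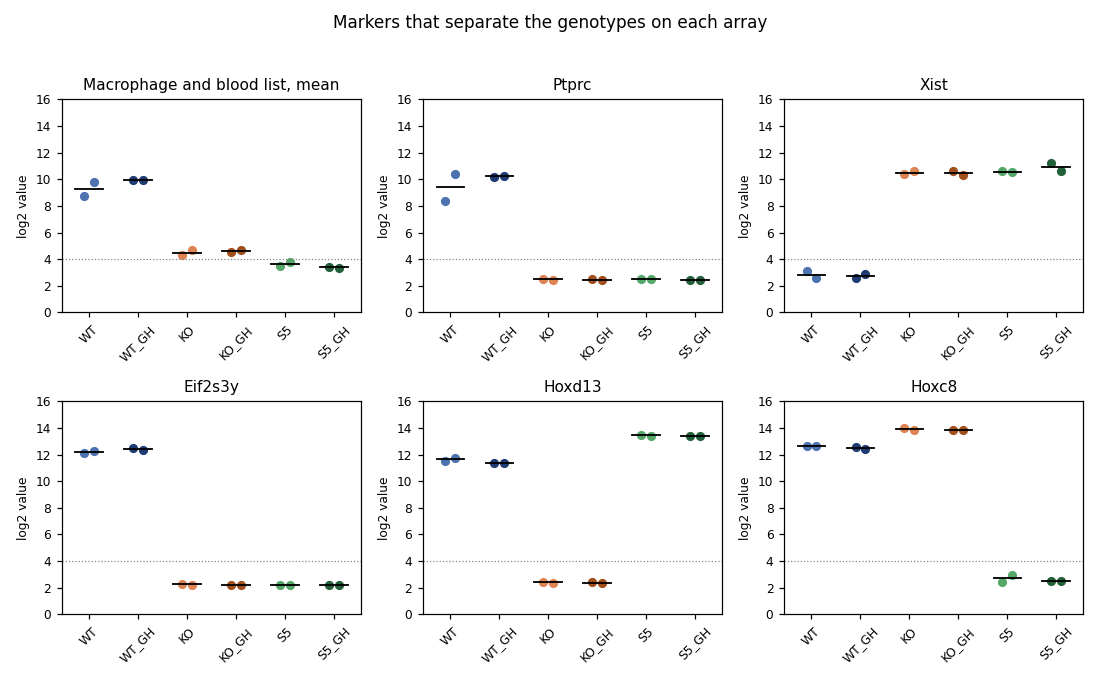
Log2 expression values (y axis, 0 to 16, dotted line at the low-mode bound of 4) of the mean of the macrophage list and of 5 genes on each array (points, 2 per group) in the 6 groups on the x axis. The macrophage mean lay between 8.73 and 9.96 on WT arrays and between 3.36 and 4.68 on KO and S5 arrays, and Hoxd13 and Hoxc8 separated S5 from KO MEFs.

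S5 and KO MEFs, which the labels give as the same cells with and without the STAT5A vector, differed untreated at homeobox genes of body position. Hoxd13, of the distal limb, was at least 690-fold higher in S5 and Hoxa10 at least 384-fold, whereas the trunk gene Hoxc8 was at least 958-fold lower and Hoxb5 at least 250-fold lower. The prostaglandin dehydrogenase Hpgd (at least 728-fold), the matrix gene Coch (at least 705-fold), the chemokine Cxcl14 (at least 646-fold), the patterning gene Msx1 (at least 265-fold) and the Wnt antagonist Sfrp2 (433-fold) were higher, and the retinoid carrier Crabp1 (at least 754-fold), the methyltransferase Nnmt (at least 429-fold), the angiotensin receptor Agtr2 (at least 488-fold) and the skeletal patterning gene Pax1 (at least 382-fold) were lower. Socs2 was higher in S5 by 4.26 (adjusted p = 4.22e-07), Cish lower by a floored -0.87 (adjusted p = 0.000563) and Igf1 lower by -3.69, and Bcl6 did not differ past the threshold (-0.10, adjusted p = 0.569). Of 47 positional genes 10 were higher and 24 lower (10 and 25 adjusted over the list alone; adjusted p = 0.000202, and 0.0474 with an estimated correlation). Cholesterol synthesis genes were higher (12 genes, 13 higher and 1 lower adjusted over the list alone; adjusted p = 1.22e-06, and 0.0474 with an estimated correlation). Smooth muscle (10 higher; adjusted p = 3.04e-05, and 0.308 with an estimated correlation), fibroblast identity (6 higher and 11 lower; 0.0126, and 0.324; the stromal antigen Cd34 floored -5.19) and cell cycle genes (11 higher and 4 lower; 0.0126, and 0.479) were called at the preset correlation only. None of the sex-linked genes differed (adjusted p = 0.997 for the list). In all 4989 genes differed, 2825 higher in S5 and 2164 lower. The Gapdh 3′ to 5′ difference was 1.46 on untreated S5 arrays and 1.02 on untreated KO arrays.

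S5 and untreated WT MEFs differed more widely, at 6307 genes (3502 higher and 2805 lower in S5). The complement gene C1qb of macrophages was at least 847-fold lower in S5, Lyz2 at least 539-fold, Crabp1 at least 553-fold, the phosphatase Ptprz1 at least 404-fold, Hoxc8 at least 399-fold and Eif2s3y at least 294-fold. Mycn was at least 1320-fold higher on the probe set tested, with log2 differences of -0.06 and -0.08 on its others. Also higher were the calcium channel subunit Cacna2d3, at least 85.9-fold, Xist, at least 94.3-fold, and the epidermal homeobox gene Dlx3, at least 28.6-fold. By Xist and Eif2s3y, cell sex differed from WT here as well. Of the STAT5 targets, Socs2 was higher in S5 by 1.71, and Cish (floored -1.01) and Igf1 (-4.90) were lower. Bcl6 was lower as well (-0.43, adjusted p = 0.012), a call lost with the mean of its probe sets (0.867) and without replicate 1 of the untreated S5 (0.0773) or replicate 2 of the untreated WT arrays (0.0707). Jak2 differed past the threshold in none of the 3 untreated comparisons (-0.02 for KO minus WT, 0.17 for S5 minus KO and 0.16 for S5 minus WT; adjusted p = 0.955, 0.117 and 0.131), though with array weights S5 minus WT passed (0.0456). Ghr did not pass either for S5 minus KO (0.06, adjusted p = 0.466; -0.32 and 0.0251 with the mean of its probe sets) or S5 minus WT (0.12, adjusted p = 0.0672), where it passed with quantile normalization (0.0244), centring (0.0481) and array weights (0.0321). Positional genes (9 higher and 29 lower; 9 and 30 adjusted over the list alone; adjusted p = 5.37e-07, and 0.0122 with an estimated correlation), NF-kB genes (13 lower, 15 adjusted over the list alone; 1.59e-07, and 0.0122) and cholesterol synthesis genes (14 lower, 15 adjusted over the list alone; 3.45e-06, and 0.0494) kept their calls with an estimated correlation. Cell cycle (23 lower; 1.1e-08, and 0.0779), macrophage (11 lower; 6.28e-07, and 0.175), interferon (3 higher and 15 lower; 0.00114, and 0.215), hypoxia (0.00368, and 0.0779), fibroblast identity (0.00368, and 0.132), immediate early (0.00661, and 0.382), matrix (4 higher and 13 lower; 0.0116, and 0.0779) and sex-linked genes (0.0128, and 0.107) did not.

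With growth hormone the genotypes differed at 5479 genes for KO against WT (2973 higher and 2506 lower in KO), 5256 for S5 against KO (2722 and 2534, or 51.8 percent higher, and 37.2 percent after centring) and 6713 for S5 against WT (3683 and 3030). Ccl3, a macrophage chemokine, was at least 794-fold lower in KO than in WT MEFs, Ccl20 at least 329-fold and Acod1 at least 470-fold, and Ccl5 was at least 668-fold lower in S5 than in WT. Cish and Socs2 were lower in KO by -3.64 and -6.09 and Bcl6 higher by 1.55, and against KO the S5 MEFs had 4.75 and 8.09 more of Cish and Socs2 on the log2 scale and less Bcl6 (-1.32). Against WT the S5 MEFs had 1.11 more Cish (adjusted p = 0.00114) and 2.0 more Socs2 (adjusted p = 1.84e-05), and Bcl6 differed by 0.23 (adjusted p = 0.119; 0.0323 without replicate 2 of the treated S5 arrays). Igf1 was lower in KO than in WT (-1.76) and in S5 than in KO (-2.65) and WT (-4.41). Ghr was 0.17 higher in S5 than in WT (adjusted p = 0.0166), a call lost with centring (0.084), without the dimmest genes (0.088), in a fit of only the groups compared (0.0583) and without replicate 1 of the treated S5 (0.0942) or replicate 2 of the treated WT arrays (0.0935). It did not pass for KO minus WT (0.06, adjusted p = 0.438) or S5 minus KO (0.12, adjusted p = 0.0977; 0.0421 with quantile normalization), nor did Jak2 in the 3 comparisons (-0.16, 0.10 and -0.07 for KO minus WT, S5 minus KO and S5 minus WT; adjusted p = 0.14, 0.416 and 0.592). Jak2 passed without replicate 2 of the treated KO arrays for KO minus WT (0.0313), and with the mean of its probe sets for S5 minus KO (-0.36, 0.0293) and S5 minus WT (-0.45, 0.00843). The surface glycoprotein Thy1 of fibroblasts was at least 1230-fold lower in S5 than in KO. In KO against WT 19 NF-kB genes were lower (adjusted p = 1.53e-18, and 0.00137 with an estimated correlation), 21 interferon genes were lower and 2 higher (5.66e-14, and 0.0287) and 17 cholesterol synthesis genes were lower (1.44e-15, and 0.0055). These are part of 14 lists called there, 8 of them also with an estimated correlation. Macrophage genes (11 lower; 1.02e-08, and 0.0892) and STAT5 targets (5 higher and 9 lower; 0.0384, and 0.0892) were called at the preset correlation only. In S5 against WT 19 NF-kB genes were lower (1.03e-11, and 0.00508) and 8 positional genes were higher and 30 lower (2e-07, and 0.0111). Against KO, S5 MEFs had 10 positional genes higher and 25 lower (0.000245, and 0.045) and 12 cholesterol synthesis genes higher (2.36e-07, and 0.045).

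To ask whether STAT5A moved the KO differences back, the 4935 genes that differed between untreated KO and WT MEFs were read in treated S5 against treated KO MEFs. Of them 3182 (64.5 percent, 95 percent interval 63.1 to 65.8) had the opposite sign. Hoxd13 and Cxcl14, lower in KO, were higher in S5. Mycn stayed high on the probe set tested, while Eif2s3y and C5ar1 stayed in the low mode. Of the 4935 genes 1994 (40.4 percent) were opposite and past the threshold, and 671 (13.6 percent) had the same sign and passed. For 3 exchangeable lines the share would be 66.7 percent over genes not selected for a difference, since KO enters both differences. Simulated exchangeable lines, shifted at every gene and with genes selected by the same test, gave 68.4 percent. With the roles of KO and S5 exchanged the share was 77.9 percent, a comparison added after the data were seen, and with selection on treated and measurement on untreated arrays it was 60 percent. In leaving out single arrays the share fell outside its interval without KO replicate 1 (66.5 percent) and 2 (66.2 percent) and without treated KO replicate 1 (67.5 percent) and 2 (61.1 percent).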

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

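The test of a gain around Mycn was set before its result was seen, and the other tests of explanations given here were chosen after. The responses to growth hormone differed between genotypes by limma's interaction test. Between WT and KO MEFs 231 genes differed (150 without either untreated S5 array and 355 without untreated WT replicate 2), and the difference of log2 changes was 3.51 for Cish, 3.55 for Socs2, -1.88 for Bcl6 (not past the threshold with the mean of its probe sets), 0.80 for Stat5a and 0.37 for Stat5b. The interferon genes and the NF-kB genes differed as lists (camera adjusted p = 3.3e-21 and 2.53e-21). Between S5 and KO MEFs 205 genes differed, with 6.11 for Cish (5.62 floored), 3.84 for Socs2 and -1.22 for Bcl6. Between S5 and WT MEFs 532 genes differed, with 2.61 for Cish (2.11 floored), -0.83 for Stat5a and -0.37 for Stat5b, and the NF-kB list differed (adjusted p = 1.92e-05). The native Stat5 genes are deleted in KO and S5 MEFs per the labels, so their differences are the change within WT MEFs against low-mode values, and their calls were lost under several alternatives, among them a trended prior.

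Signal also lay outside the genes compared. Of 10092 probe sets with no single gene listed, 101 changed with growth hormone in WT MEFs (65 up and 36 down), 428 in S5 MEFs (332 up and 96 down) and 24 in KO MEFs (19 up and 5 down).

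The rise of inflammatory genes with growth hormone in WT MEFs was weighed first. More macrophages on the treated WT arrays are argued against as the whole cause: the macrophage list had a median change of 0.50 (SD of its members 0.73), and -0.07 and 1.10 without untreated WT replicates 1 and 2, against 3.21 for the inflammatory list (3.16 floored). Macrophages in the WT cultures alone, answering the treatment, stay open: 34 percent of the genes that rose at least 2-fold in WT lay in the low mode on every array of the other genotypes, against 16.5 percent for S5 (one-sided Fisher exact p = 2.78e-06). That p-value takes genes as independent and the sets as separate, although some genes rose in both, so no weight is put on it. An inflammatory stimulus in the treatment that needs no STAT5 also stays open, since the inflammatory list rose in KO MEFs (adjusted p = 0.00101 with an estimated correlation), and no vehicle group tests it. A part of the WT minus KO difference at Il1b, Tnf and Saa3 may therefore reflect cell composition and not STAT5. A direct STAT5 effect in fibroblasts remains as a biological alternative that was not tested on its own. In S5 MEFs, where Cish and Socs2 rose, Il1b stayed in the low mode. Tnf and Saa3 had no floored rise there, since their floored differences from the WT response equal the whole floored rise in WT. The inflammatory list still rose in S5 MEFs (median 1.29). S5 MEFs carry STAT5A without STAT5B and lack the macrophage signal of WT arrays, so these values do not decide it.

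The differences of KO and S5 MEFs at very many genes came next. A full return of S5 MEFs to the wild-type state is argued against, since untreated S5 and WT MEFs differed at 6307 genes. Of the KO minus WT genes 64.5 percent had the opposite sign in S5, below the 77.9 percent of the mirror comparison. The mirror share depends on which line lies farthest from the others, so it does not measure a return. For 3 exchangeable lines, with no return, the share would be 66.7 percent (68.4 percent simulated), which 64.5 percent does not exceed. Simulated cells identical to WT gave 99.6 percent, but KO was shifted there at every gene and 15881 genes were selected, so that share is no benchmark. The macrophage and Y-linked transcripts of WT arrays and the Gapdh 3′ to 5′ difference of S5 arrays may bear on the 64.5 and 77.9 percent and on the 6307 genes. The 64.5 percent thus shows no return, but a partial return stays open. Swapped labels are argued against by the Stat5a probe set read in S5 MEFs, at 9.04 or more on every array labelled S5 and at 2.25 or less on every array labelled KO. Different isolates or clones stay open: 72.3 percent of positional genes differed between S5 and KO, against 27.3 percent of other genes. Positional genes also differed between untreated KO and WT MEFs (14 higher and 17 lower of 47). Effects of STAT5A, of the vector and of selection in culture also stay open, since no KO group with an empty vector is among the 6 groups.

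The Mycn difference was weighed last. A loss of STAT5 that STAT5A undoes is argued against, since S5 minus KO was 0.18 (95 percent interval 0.10 to 0.27), although a change that STAT5A does not undo stays open. A gain that reaches the flanking genes on both sides in both lines is argued against: Ddx1 differed from WT by -0.13 in KO and 0.30 in S5, and Cyria by -0.64 in S5. Cyria was 1.06 higher in KO (adjusted p = 0.0183). Beyond Ddx1, Nbas differed from WT by 0.84 in S5 (adjusted p = 0.00147) and -0.22 in KO, and the next gene, Trib2, by -1.3 in S5. Nbas and Trib2 were chosen after their values were seen. A gain on the Cyria side in KO MEFs, on the Ddx1 side in S5 MEFs, or of Mycn alone stays open. A probe set that reads something other than the Mycn transcript may account for the signal. On another Mycn probe set KO minus WT was 0.19 and S5 minus WT was -0.06, and on the remaining one they were -0.06 and -0.08. Both lay in the low mode in every group, so a gain of Mycn alone has no sign on them. What the probe set with the signal reads was not tested.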

How the results depend on the processing

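The alternatives above the low mode, with crossed pairing, with a background above the low mode and with KO and S5 exchanged were chosen after the data were seen. Where a count moved by more than 1.5 times the cause was not tested, except that a 2-fold minimum lowers counts by construction. With growth hormone in WT MEFs the count of 1092 was 266 in a fit of only the groups compared and 465 at 2-fold or more. For S5 (1433) it was 2914 with array weights, 532 with only the groups compared and 419 at 2-fold. For KO (56) it was 10 with weights, 0 by limma with only the groups compared (1407 at an unadjusted p below 0.05), 24 at 2-fold and 95 above the low mode. The WT against KO responses (231) gave 129 without the dimmest genes, 125 with weights and 116 with only the groups compared. The S5 against KO responses (205) gave 314 over every probe set and 114 with only the groups compared, and S5 against WT (532) gave 825 with weights. At 2-fold the genotype counts were 2061 and 2424 for KO against WT without and with the hormone, 2299 and 2409 for S5 against KO (3494 with the hormone and only the groups compared), and 2979 and 3327 for S5 against WT. The overlaps of WT with S5, WT with KO and S5 with KO were 78, 12 and 12 at 2-fold, and the 36 genes became 19. The 64.5 percent moved to 60 percent with selection on treated arrays, and the 86 list calls became 28 with an estimated correlation.

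No label says what a shared replicate number marks, and the deviations of the arrays neither show nor exclude a pairing. The deviations of same-numbered arrays correlated above 0.1 in 1 of 15 pairs of groups (0.197) and below -0.1 in 3 (lowest -0.363). With the replicate number as a block the KO count was 32, the overlaps of KO with WT and S5 were 16 and 17, and the 36 genes became 23. The other counts stayed within 1.5 times under the block (881 in WT, 1173 in S5, 174 and 180 for the responses against KO). Crossing the pairing of the KO arrays gave 104.

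Leaving out each array in turn, with a lone array assumed to vary like the other groups, gave 547 to 1143 genes for WT, 552 to 1536 for S5 and 20 to 140 for KO. The responses gave 150 to 355 (WT against KO), 155 to 263 (S5 against KO) and 363 to 580 (S5 against WT). Genotype counts ranged over 3518 to 5125 and 4183 to 5442 (KO against WT without and with the hormone), 3661 to 5121 and 4075 to 5312 (S5 against KO), and 4780 to 6483 and 5564 to 6853 (S5 against WT). The overlaps ranged over 121 to 318, 14 to 57 and 14 to 45, the 36 genes over 15 to 68, the reversal over 61.1 to 67.5 percent and the list calls over 81 to 91. No named gene reversed when an array was left out. With the mean of all probe sets the S5 minus KO difference reversed for Stat5a (3.81, and 3.41 with the hormone), because the mean includes the probe set that reads S5 MEFs, for Ghr (-0.32) and for Jak2 with the hormone (-0.36). No list reversed in any alternative. The growth hormone response of KO MEFs was the least stable of the 3: of its named genes 57 values lost the call under other settings and 90 when an array was left out, against 22 and 20 in WT and 10 and 4 in S5. The low mode hides differences among the 39.8 percent of genes with a mean below 4.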

Other observations

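No tests of explanations were made for the values here. The poly-A spike-in controls were higher on treated than on untreated arrays in each genotype, at 10.64 against 10.09 in WT, 10.82 against 10.42 in KO and 10.90 against 10.48 in S5 (means of 2 arrays). The 2 untreated WT arrays differed in Ptprc, a pan-leukocyte gene chosen after its values were seen, at 8.39 and 10.38. Vsnl1, a calcium sensor gene on the same side of Mycn as Cyria, also chosen after its values were seen, was 2.38 higher in KO than in WT and lower in S5 (-2.68).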
